A study of Caenorhabditis elegans with 2 samples.

How the data were processed

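The study applied ChIP-seq to an eGFP-tagged NHR-12 in whole mixed-stage C. elegans embryos, with 2 biological replicates of 1 group, per the labels. Both are labelled as separate biological replicates of 1 strain, and what was separate about them (culture or collection) is not stated. Deposited for each of the builds ce11 and ce10 were a thresholded peak list, a list of candidate regions called on the pooled replicates, and a list of 30000 candidate regions called on each replicate. Per the description files deposited with the libraries, each replicate's candidates were derived from its own alignments and a control. The pooled candidates came from both replicates' alignments and a control, and the thresholded peaks, deposited as the optimal set, from comparing the candidate lists by the irreproducible discovery rate (IDR). The aligner, the peak caller, their versions and the IDR threshold were not given in the sources used here. The 8 deposited region lists matched the checksums in those description files (8 of 8).

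The authors deposited the lists in narrowPeak format without a header line. Each region carries a signal that the authors' peak caller computed against the control, whose scale is not stated, and a value that by the format is −log10 of the q value, also the authors'. The size of the signal was not compared between lists, and across lists it was used only in correlations and given side by side. The −log10 q values are capped: 203 of the 249 thresholded peaks held the highest value of their list, so signal was used for ranking. Values of at least 2 on that scale were held by 187 regions of replicate 1, 437 of replicate 2 and 261 of the pooled candidates. Regions had a median width of 356 bp in the pooled list and 376 bp in both replicate lists. Neither the lists nor the labels give read counts, so the depth per sample and the precision of a signal value are unknown.

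Coordinates are 1-based on ce11. The ce10 lists were used only for the number of peaks and the replicate comparisons, and no coordinate was converted between builds. Gene starts, biotypes, exons, introns and UTRs came from Ensembl release 115 for the assembly WBcel235 (46890 genes), and sequence from the RefSeq copy of the same assembly; WBcel235 and ce11 are names of the same assembly. A gene had a peak or candidate when a summit lay from 1000 bp upstream to 200 bp downstream of its start. Regions were taken as overlapping from 1 bp. The background of most tests was the 28282 pooled candidates that overlap no thresholded peak, since these could have been called.

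Before the data were examined, the groups, tests, 31 gene lists, 20 motifs, most alternatives and the rule for named genes were fixed. The rule took the nearest gene start to the 20 peaks with the largest signal, up to 5 members with a peak by signal from every list with adjusted p below 0.05, nhr-12, unc-119, and up to 10 nuclear hormone receptor genes with a peak. Other names are of genes chosen after their values were seen. Gene lists, location and chromosome X were tested with Fisher's exact test, motifs with an exact McNemar test of summit windows (100 bp each side) against 1 flank 400 bp to a randomly chosen side, and GC content with a permutation test of 100000 resamples. Replicate top lists, each of 249 regions, were compared with 1000 circular shifts along the chromosomes. All tests were two-sided but that of the shifts and that of the start-window share against GC-matched candidates. Adjusted p-values are Benjamini-Hochberg within each family, intervals of shares are exact Clopper-Pearson at 95%, and the interval of the rank correlation came from 1000 bootstrap draws of peaks. Units of these tests are regions or genes, so p-values do not measure the spread between the 2 replicates. Agreement between replicates is given by the overlap, and by repeating results with the 249 best regions of a single replicate. In that repeat, chromosome X and the start-window share were set against the pooled candidates overlapping none of those regions. That background still drew on both replicates.

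The annotation classes, distances to coding starts, small RNA genes within 50 bp of summits, the test of each biotype, motifs by class of peak, and the comparisons with randomly drawn candidates were added after seeing the data. Random draws took as many candidates as peaks, 2000 times, either freely, matched on GC content in bins of 2 percentage points, or matched on GC content and on lying in a start window.

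The code was tested on simulated data. With 15000 genes and no effect, 5.00% of lists of 30 genes and 8.00% of lists of 360 gave p below 0.05 in 100 simulations each. A true odds ratio of 8 was called in 92.0% of lists of 30 genes. For 249 pairs of windows, a motif in 10% of summits and 5% of flanks was called in 48.0% of 200 simulations, and 1 in 20% of summits in 100.0%. Calls in all simulations were at p below 0.05 without adjustment, which is less strict than the adjusted tests. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 with fixed random seeds.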

Results

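The data were lists of genomic regions from chromatin immunoprecipitation with sequencing (ChIP-seq) of NHR-12, a member of the large nuclear hormone receptor family of the nematode Caenorhabditis elegans. The receptor carried an enhanced green fluorescent protein tag in strain OP318, whose transgene lies in a background with a mutation in unc-119, the gene commonly used as the rescue marker for such insertions. Whole mixed-stage embryos of pooled sex made up 1 group with 2 biological replicates, per the labels, which also give a fragment size range of 150 to 350 bp. The labels name no second condition, so the question that the design poses is where in the genome the tagged receptor was enriched and how alike the replicates were. The labelled control was not analysed here. Read counts per library were not in the sources used here, so the depth behind each signal value is unknown, and intervals below describe counts of regions or genes only.

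On the ce11 build, the thresholded list held 249 peaks. The peak with the largest signal, 113, lay 80 bp upstream of the start of atx-2, which encodes the worm ataxin-2 RNA-binding protein (chromosome III, 10461276 to 10461399). It ranked 1 among the candidates of replicate 1 (signal 68.1) and 3 among those of replicate 2 (signal 46.8). Signal is the authors' own value for each region on a scale that the sources do not state, and it is used here to rank and describe regions and to correlate the replicates. Values from different lists that stand side by side are not compared in size. Across the 249 peaks the signal ran from 30.7 to 113 with a median of 39.2. They were the 249 regions with the largest signal among 28574 candidates called on the pooled replicates, and the best candidate below them had a signal of 30.6.

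Of the 20 peaks with the largest signal, 15 lay nearest to the start of a protein-coding gene, 15 lay within 1000 bp upstream to 200 bp downstream of an annotated start, and 18 lay outside protein-coding genes and the bodies of small RNA genes. Summits fell 145 bp upstream of C16C10.4 (signal 90.4), 65 bp upstream of tasp-1, a taspase (signal 88.9), and 15 bp upstream of spe-48 (signal 84.9). Close upstream positions were also found at the ribosomal protein gene rpl-3 (307 bp, signal 84.0), ears-2, a glutamyl-tRNA synthetase gene (31 bp, signal 76.7), and egl-30, which encodes a Gq alpha subunit (53 bp, signal 74.2). The same held for C02F5.12 (34 bp), B0495.9 (54 bp), K05C4.7 (219 bp), Y87G2A.25 (346 bp) and nspc-17 (749 bp). Summits near F20B6.9 (1776 bp), Y48G10A.3 (1476 bp) and nhr-20, another nuclear hormone receptor gene (4648 bp), lay farther upstream, outside the window.

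The nearest start was non-coding at the other 5 of these 20 peaks. The peak with the second largest signal, 109, lay on chromosome X at 11094167 to 11094269, 1471 bp upstream of the tRNA gene WBGene00014538. At chromosome I, 13463785 to 13464140, a summit lay 8 bp inside rpr-1, the RNA component of ribonuclease P, which is nested in an intron of the Integrator subunit gene ints-8 (signal 82.4). Summits lay 53 bp inside F36H1.17 (signal 77.5) and 772 bp upstream of the ncRNA gene WBGene00220175 (signal 63.9). The peak nearest to C41A3.6, 10035 bp from its start, had its summit in a coding exon of the polyketide synthase gene pks-1 (signal 76.0).

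Every one of these 20 peaks ranked 59 or better in replicate 1 and 123 or better in replicate 2. The lowest of the replicate 2 ranks was at spe-48, which ranked 3 in replicate 1. High ranks in both replicates go with the choice of these peaks on pooled signal, to which both contribute, and the shares of peaks below are subject to the same limit. A replicate 1 candidate overlapped 249 of the 249 peaks, and a replicate 2 candidate overlapped 248; the exception lay on chromosome I at 1874042 to 1874397, in a coding exon of tub-2. Of the peaks, 177 (71.1%, exact 95% interval 65.0 to 76.6) were among the 249 best regions of replicate 1, and 149 (59.8%, 53.5 to 66.0) among those of replicate 2. Both top lists held 100 of the peaks, and 23 were in neither.

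The top 249 regions of replicate 1 overlapped those of replicate 2 in 41.8% of cases (exact 95% interval 35.6 to 48.2). Regions shifted along their chromosomes shared 0.203% on average and 1.20% at most (one-sided permutation test, p = 0.001, the smallest that 1000 shifts can give). Across the 248 peaks with a candidate in both replicates, Spearman's rho between replicate signals was 0.150 (bootstrap 95% interval 0.0114 to 0.280) and Pearson's r of log2 signal was 0.19. Both are correlations across regions, which are not independent replicates. The peaks were the regions with the largest pooled signal, to which both replicates contribute, and such a choice can lower a correlation within the set, so these values do not measure how well the replicates agree. Over the 9413 pooled candidates with a candidate in both replicates, rho was 0.164. These were 32.9% of the 28574 pooled candidates and were chosen by being called in each list. This value therefore does not measure the agreement of the replicates either.

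**Figure D1:**
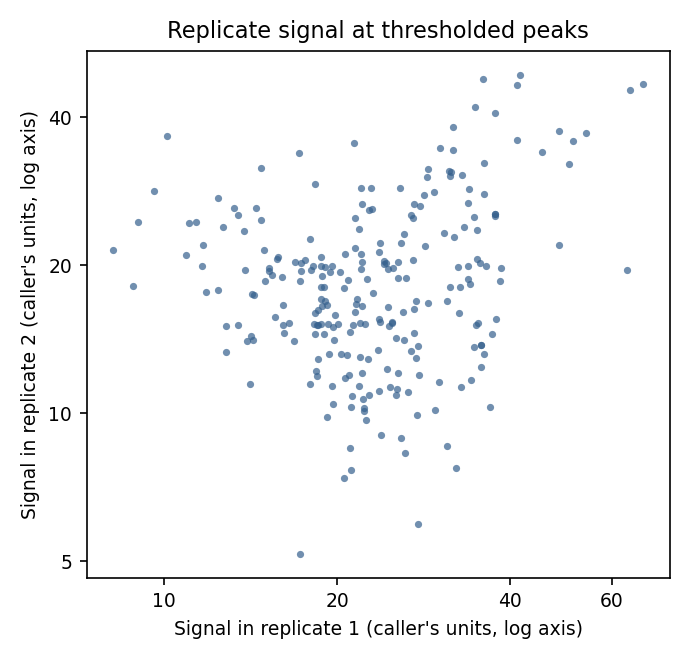
Signal of the best overlapping candidate in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), in the units of the authors' peak caller. Each point is 1 of the 248 thresholded peaks with a candidate in both replicates, and Spearman's rho in this set, chosen on pooled signal, was 0.150.

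Peaks were concentrated just upstream of genes. Of the 249 summits, 195 (78.3%, exact 95% interval 72.7 to 83.3) lay within 1000 bp upstream to 200 bp downstream of an annotated gene start, against 10855 of the 28282 candidates that overlap no peak (38.4%). The odds ratio was 5.80 (95% interval 4.26 to 7.997; Fisher's exact test, two-sided, p = 2.06e-37). With starts of protein-coding genes alone the shares were 53.8% and 24.8%, an odds ratio of 3.54. Candidates matched to the peaks on GC content gave 38.2%. The 249 best regions of replicate 2 alone gave a smaller odds ratio, 3.57, and those of replicate 1 alone gave 5.41.

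By annotation, 156 summits (62.7%) lay outside protein-coding genes and the bodies of small RNA genes (tRNA, snoRNA, snRNA, rRNA and microRNA), a class that includes summits inside other non-coding genes such as F36H1.17, against 34.9% of candidates (odds ratio 3.13, adjusted exact p = 1.88e-18). Only 5 summits (2.01%) lay in coding exons, against 28.6% (odds ratio 0.0511, adjusted exact p = 3.48e-28). Introns of protein-coding genes held 55 (22.1% against 30.5%, adjusted exact p = 0.00542) and 3′ UTRs held 2 (0.803% against 3.59%, adjusted exact p = 0.0173). The 6 summits in 5′ UTRs did not differ detectably from the candidates' share (2.41% against 1.86%, adjusted exact p = 0.476). Bodies of small RNA genes held 25 summits (10.04% against 0.484%, odds ratio 22.9, 95% interval 14.04 to 36.1). The median distance from a summit to the nearest protein-coding start was 545 bp for peaks and 1461 bp for candidates, and 101 peaks (40.6%) lay within 500 bp upstream of such a start, against 11.3% of candidates.

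**Figure D2:**
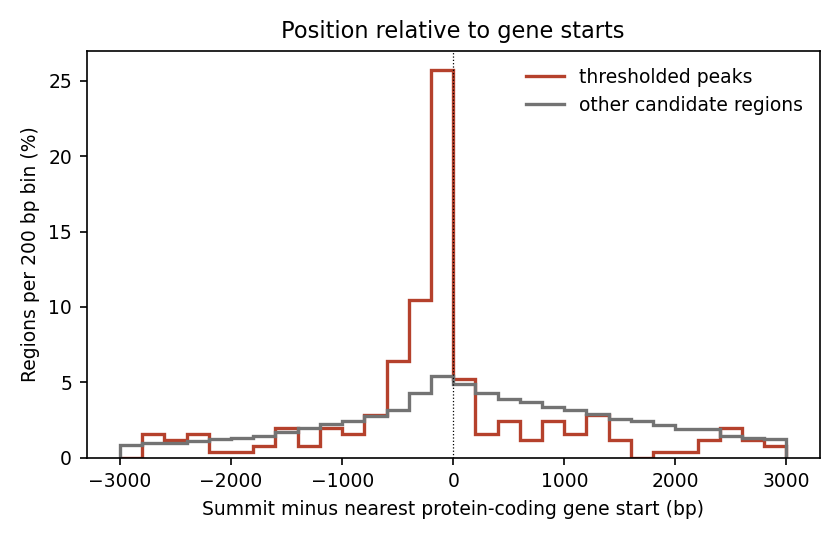
Share of regions per 200 bp bin (vertical, percent) by the distance of the summit from the nearest protein-coding gene start (horizontal, bp, negative values upstream), for 249 thresholded peaks and 28282 other candidates. The bin just upstream of the start holds 25.7% of peaks and 5.41% of candidates.

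Genes near peaks were tested against 31 gene lists fixed before the data were examined. The background was the 14976 genes with any pooled candidate summit in the start window, of which 373 had a peak there. It includes 3315 piRNA genes, of which 11 had a peak, and these lower the share among the other genes in each comparison. Core histone, ribosomal protein, chaperone, tRNA, snRNA and snoRNA genes were over-represented, and pseudogenes were under-represented (Fisher's exact test, two-sided, Benjamini-Hochberg over 31 lists). In all, 74 of the 249 peaks (29.7%) had a start from 1 of the 6 over-represented lists in the window. The tests treat genes as units, so they describe these lists and not the spread between replicates, and genes that share a promoter or a peak are not independent.

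Of 28 core histone genes with a candidate, 9 had a peak (32.1% against 2.44% of other genes; odds ratio 19, 95% interval 7.50 to 44.3, adjusted exact p = 2.36e-07). These 9 genes shared 5 peaks, and at 4 of them the peak lay between 2 genes placed head to head. The peak between his-31 and his-32 (chromosome IV, 8333957 to 8334312) had a signal of 55.7, with 27.1 in replicate 1 and 24.9 in replicate 2. Between his-67 and his-68 (chromosome I, 9988803 to 9989158) the signal was 50.8, and next to his-61 it was 40.005. Histone genes occur in near-identical copies, so where reads were assigned among them is uncertain.

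Ribosomal protein genes had a peak in 11 of 66 cases (16.7% against 2.43%, odds ratio 8.03, 3.76 to 15.7, adjusted exact p = 4.82e-06), from 11 different peaks. After rpl-3, the largest signals were at rps-12 (60.05, 160 bp upstream), rpl-35 (50.3), rps-28 (49.97) and rpl-15 (49.2). Some of these peaks lay nearer to another protein-coding start. That was so at rps-12 (ska-3, 133 bp), rpl-22 (ify-1, 173 bp against 264 bp) and rps-26 (tmem-107, 8 bp against 465 bp). Chaperone genes had 5 of 32 (odds ratio 7.33, 2.19 to 19.5, adjusted exact p = 0.00478). They were hsp-3, an endoplasmic reticulum Hsp70 (signal 53.8, 47 bp upstream), hsp-60, the mitochondrial chaperonin (51.2, 614 bp upstream), and the DnaJ-type genes dnj-29 (36.4), dnj-13 (36.1) and dnj-19 (32.02). The hsp-3 peak had signals of 17.2 in replicate 1 and 33.9 in replicate 2, and the hsp-60 peak 37.7 and 15.5. The hsp-60 peak lay nearer to the start of Y22D7AL.10 (199 bp). Ranks in replicates 1 and 2 were 368 and 18 for hsp-3, 15 and 280 for hsp-60, and 263 and 192 for dnj-29. They were 6545 and 56 for dnj-13, and 145 and 2037 for dnj-19. None of these 5 peaks was thus among the 249 best regions of both replicates. The chaperone call was lost for the 124 peaks with the largest signal (odds ratio 4.96, adjusted exact p = 0.350), with the best regions of replicate 1 alone (2.70, adjusted exact p = 0.418) and with 1 gene counted per peak (5.09, adjusted exact p = 0.215).

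Among small RNA genes, 29 of 203 snoRNA genes had a peak (14.3% against 2.33%; odds ratio 6.99, 4.48 to 10.6, adjusted exact p = 7.31e-13). F54E7.10 and F54E7.11 lie in the rps-12 locus and share its peak, and 3 of the 26 peaks behind the snoRNA genes also had a ribosomal protein start in the window. The next snoRNA genes by signal were T03F7.8 (59.3, 21 bp upstream), T02E1.9 (57.7, 31 bp upstream) and F55A11.10 (54.1, 5 bp upstream). Of 363 tRNA genes 27 had a peak (7.44% against 2.37%; odds ratio 3.31, 2.12 to 4.99, adjusted exact p = 4.43e-06). The largest signals were at WBGene00000308 (62.5, 10 bp inside the gene), WBGene00023042 (59.3), WBGene00022913 (54.1), WBGene00014406 (53.6) and WBGene00023221 (51.2). The last of these peaks lay 956 bp upstream of its tRNA gene, with its summit 13 bp inside the snoRNA gene ZK994.7. No protein-coding start lay in the window of 22 of the 25 peaks behind these tRNA genes, against 12 of the 26 behind the snoRNA genes and 2 of the 7 behind the snRNA genes below. Many tRNA genes are near-identical copies, so the assignment of reads to any of them is uncertain.

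The snRNA genes with a peak numbered 7 of 58 (12.1% against 2.45%; odds ratio 5.46, 2.07 to 12.2, adjusted exact p = 0.00293). Those with the largest signals were the spliced leader genes sls-2.2 (59.3, 1 bp from the start) and sls-2.4 (54.3), then T11F9.15 (36.3), F38E11.11 (34.1) and sls-2.8 (33.9). The call was lost for the 124 peaks with the largest signal (odds ratio 2.65, adjusted exact p = 0.511) and with replicate 1 alone (3.01, adjusted exact p = 0.177). Summits lay within 50 bp of a tRNA gene in 24 peaks (9.64% against 0.566% of candidates; odds ratio 18.7, 11.4 to 29.6). They lay as close to a snoRNA gene in 13 (odds ratio 24.3) and to an snRNA gene in 6 (odds ratio 38.7). Only 1 summit lay as close to a microRNA gene (odds ratio 3.56, adjusted exact p = 0.251).

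Pseudogenes had a peak in 1 of 452 cases, WBGene00009972 (odds ratio 0.0844, 0.00213 to 0.475, adjusted exact p = 0.00182). That call was lost with the best regions of replicate 2 alone (0.290, adjusted exact p = 0.0924) and against randomly drawn candidates (1 gene observed, 4.44 expected, permutation p = 0.130).

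Nuclear hormone receptor genes, the tagged protein's own family, had a peak in 2 of 84 cases (2.38% against 2.49% of other genes; odds ratio 0.955, 0.113 to 3.58, adjusted exact p = 1.00). These were nhr-256 (chromosome V, 1743446 to 1743801, 147 bp upstream, signal 49.5) and nhr-47 (chromosome V, 5505030 to 5505385, 45 bp upstream, signal 32.02). The nhr-47 peak is the same as that of dnj-19. No peak was found in the start window of any of the 66 genes for cuticle collagens and moulting with a candidate (odds ratio 95% upper limit 2.25, adjusted exact p = 0.695). Counts were also 0 for 18 bHLH, T-box and GATA factors, 25 respiratory chain and ATP synthase genes, 30 cytochrome P450 genes, 13 UDP-glucuronosyltransferases, 20 body wall muscle markers, 34 neuron markers, 23 cilium genes, 3 rRNA genes and 1 vitellogenin gene (adjusted exact p = 1.00 for each).

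The remaining lists also missed the threshold. The list of pharynx markers, which takes in all genes named pqn for a glutamine- and asparagine-rich domain, had 3 of 30, all of them pqn genes (pqn-59, pqn-21 and pqn-70; adjusted exact p = 0.147), and germline and oocyte markers 3 of 34 (egg-5, spn-4 and puf-9; adjusted exact p = 0.173). Translation factors and tRNA synthetases had 3 of 35 (iff-2, ears-2 and erfa-3; adjusted exact p = 0.173), and microRNA genes 7 of 137 (adjusted exact p = 0.244). Both of these lists were over-represented with the best regions of replicate 1 alone, as were translation factors and tRNA synthetases with 1 gene counted per peak and microRNA genes with all annotated genes as background. Fatty acid metabolism had 3 of 48 (adjusted exact p = 0.302), cell cycle and replication 3 of 62 (adjusted exact p = 0.444), splicing factors 2 of 37 (adjusted exact p = 0.486), and antimicrobial and immunity effectors 2 of 102 (adjusted exact p = 1.00). A single gene had a peak in the lists of intestine markers (cpr-9, adjusted exact p = 0.436), epidermis markers (wrt-3, adjusted exact p = 0.506), proteasome subunits (rpn-7, adjusted exact p = 0.695), glutathione S-transferases (gst-27, adjusted exact p = 0.695) and homeobox genes (ceh-38, adjusted exact p = 0.956). Genes in these lists other than ears-2 were named after their values were seen. In simulations with 15000 genes, a true odds ratio of 4 was called at unadjusted p below 0.05 in 56% of lists of 30 genes and 98% of lists of 200. The simulated genes were independent and p was not adjusted over lists, so these shares overstate what the adjusted tests could call.

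**Figure D3:**
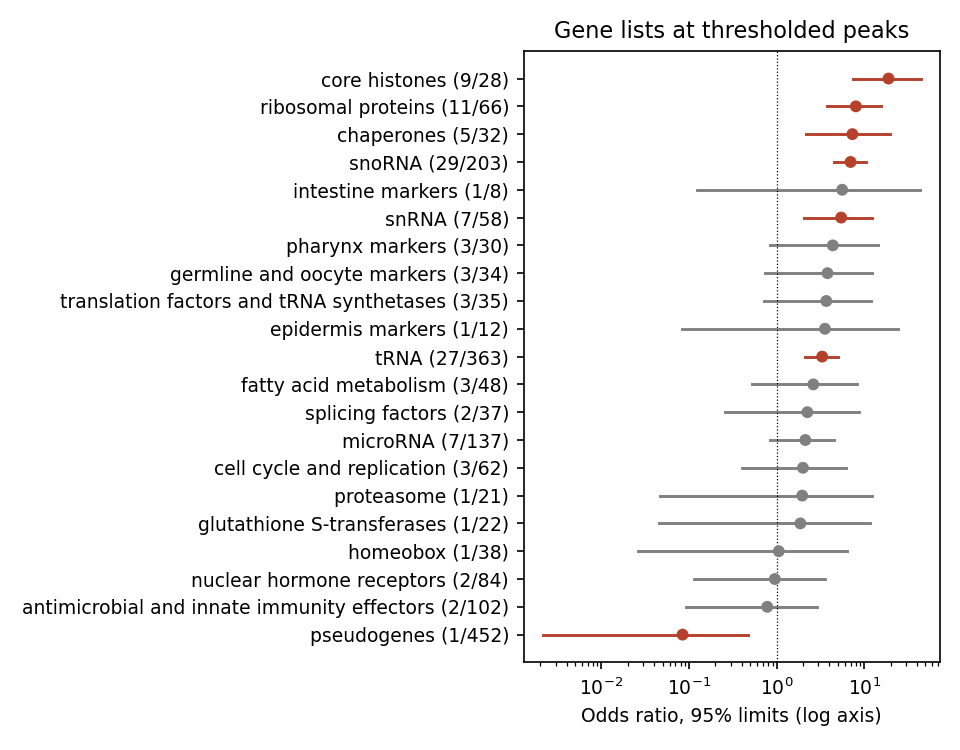
Odds ratio (horizontal, log axis) of having a thresholded peak in the start window for the members of each gene list with at least 1 such gene, with 95% limits as bars. Counts in brackets are members with a peak over members with a candidate. Red marks the 7 lists past an adjusted p of 0.05, from core histones at 19 to pseudogenes at 0.0844.

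Sequence within 100 bp of the summits differed from flanks 400 bp away in 8 of 20 motifs fixed before the data were examined (exact McNemar test, two-sided, Benjamini-Hochberg over 20 motifs). The promoter element CTGCGTCT occurred in 32 of 249 summit windows (12.9%) and 3 flanks (odds ratio of discordant pairs 15.5, 3.94 to 134, adjusted exact p = 2.62e-06). The GC box, a site of the Sp1 and KLF type, occurred in 46 and 12 (4.78, 2.30 to 11.1, adjusted exact p = 2.04e-05). The GA repeat GAGAGAGA occurred in 28 and 6 (6.50, 2.26 to 25.6, adjusted exact p = 0.000295), and the B box, the internal promoter element of tRNA genes, in 18 and 1 (18, 2.84 to 750.0, adjusted exact p = 0.000295). These 4 motifs also stood above candidates matched on GC content, with odds ratios from 2.24 for the GC box to 6.36 for the B box and adjusted p of 0.01 or below by permutation. For the B box this does not separate the motif from tRNA genes. Candidates were not matched on closeness to tRNA genes, and 14 of the 18 summits with a B box were at them. The GA repeat missed the threshold among the 124 peaks with the largest signal (odds ratio 5.50, adjusted exact p = 0.0749).

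Fewer summits than flanks held the GATA site TGATAA (16 against 47, odds ratio 0.326, adjusted exact p = 0.000295), a run of T (24 against 58, 0.358, adjusted exact p = 0.000295), the homeodomain core TAATTA (15 against 33, 0.438, adjusted exact p = 0.0324) and the RFX-type X-box (0 against 7, adjusted exact p = 0.0391). None of these 4 calls held against GC-matched candidates, where the odds ratios were 0.621 for GATA, 1.39 for the T run, 1.82 for the homeodomain core and 0 for the X-box (adjusted p from 0.177 to 0.309 by random draws, a permutation test). With the best regions of replicate 1 alone the X-box odds ratio was 1.5, and with those of replicate 2 alone the homeodomain core missed the threshold (0.417, adjusted exact p = 0.0608).

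The hexamer AGGTCA, recognised by many nuclear receptors, was present at 13 summits and 7 flanks (odds ratio 1.86, 0.689 to 5.50, adjusted exact p = 0.405). Its share of 5.22% at summits stood beside 5.70% of candidates. The extended form AAGGTCA occurred at 4 summits and 3 flanks, and the direct repeat DR1 at 0 of each. For AGTGCA the counts were 23 and 13 (adjusted exact p = 0.221). With 50 bp each side they were 13 and 3 (odds ratio 4.33, adjusted exact p = 0.0608). For the 124 peaks with the largest signal they were 13 and 4 (3.25, adjusted exact p = 0.140). AGTGCA passed under no alternative, and its odds ratio against GC-matched candidates was 1.11. AGTTCA occurred at 12 summits and 25 flanks (odds ratio 0.458, adjusted exact p = 0.0910) and was rarer than in candidates (4.82% against 12.7%, adjusted exact p = 0.000162). It was also past the threshold with the opposite flank (0.321), with either replicate alone (0.370 and 0.414) and against GC-matched candidates (0.472), but not with 50 bp each side (0.583, adjusted exact p = 0.653) or for the 124 peaks with the largest signal (0.538, adjusted exact p = 0.479). The TATA element, CACC box, E-box, heat shock element, bZIP, AP-1 and forkhead sites did not pass against flanks, with adjusted exact p from 0.144 to 1.00. Against candidates, however, the CACC box was more frequent (odds ratio 2.46, adjusted exact p = 0.00346) and the TATA element rarer (0.560, adjusted exact p = 0.00760), and with the opposite flank both passed as well (4.5, adjusted exact p = 0.0109, and 0.524, adjusted exact p = 0.0375). Neither passed with 50 bp each side, for the 124 peaks with the largest signal (where TATA was at 1.15), with either replicate alone, or against GC-matched candidates (1.42 for the CACC box and, in the other direction, 1.35 for TATA; adjusted permutation p = 0.309 for each).

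GC content was 46.9% ± 6.06 (SD, 249 summit windows), against 38.2% ± 6.84 in the other candidates and 36.4% ± 7.85 in the flanks. The difference from candidates was 8.75 percentage points (permutation test, two-sided, p = 1e-05, the smallest that 100000 resamples can give).

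**Figure D4:**
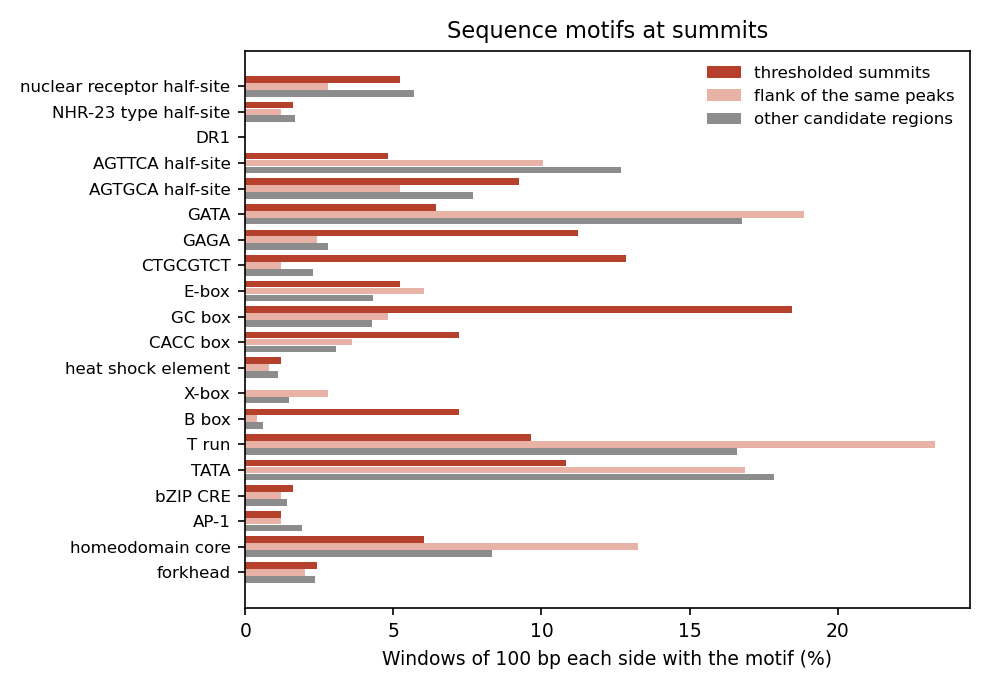
Share of windows of 100 bp each side with each of 20 motifs (horizontal, percent) at thresholded summits, in 1 flank of the same peak and at the other candidates. The GC box is in 18.5% of summit windows and 4.82% of flanks, and the GATA site in 6.43% and 18.9%.

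Chromosome X held 61 of the 249 peaks (24.5%, exact 95% interval 19.3 to 30.3), against 18.8% of the other candidates (odds ratio 1.4, 1.03 to 1.88, Fisher's exact test, two-sided, p = 0.0276). Chromosome III held 50 (20.1% against 14.8%), I 40, IV 34, II 33 and V 31 (12.4% against 17.7%); these shares were not tested. The X call was lost for the 124 peaks with the largest signal (1.38, exact p = 0.134) and with either replicate alone (1.22 and 1.28). It was also lost without the peaks and candidates that had a tRNA start in the window (1.17, exact p = 0.342), an alternative chosen after seeing the data.

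At the tagged gene itself, nhr-12 (WBGene00003611, chromosome V, 10082133 to 10084049, minus strand), no region lay within 1000 bp in the thresholded list, the pooled candidates or either replicate's 30000 candidates. The stretch of chromosome V around it without a pooled candidate ran from 10043966 to 10106564, or 62599 bp, and overlapped 20 protein-coding genes. In replicate 1 it was 59372 bp long and in replicate 2 60575 bp. At unc-119 (WBGene00006843, chromosome III, 10902641 to 10908935, plus strand), 5 pooled candidates lay within 1000 bp. The best of these, at 10906235 to 10906590, had a signal of 19.3 and rank 1280, and the locus held no thresholded peak. The best candidate of replicate 1 there, at 10906225 to 10906600, ranked 593. That of replicate 2 was another region, at 10909585 to 10909960, past the gene end, and ranked 4259.

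**Figure D5:**
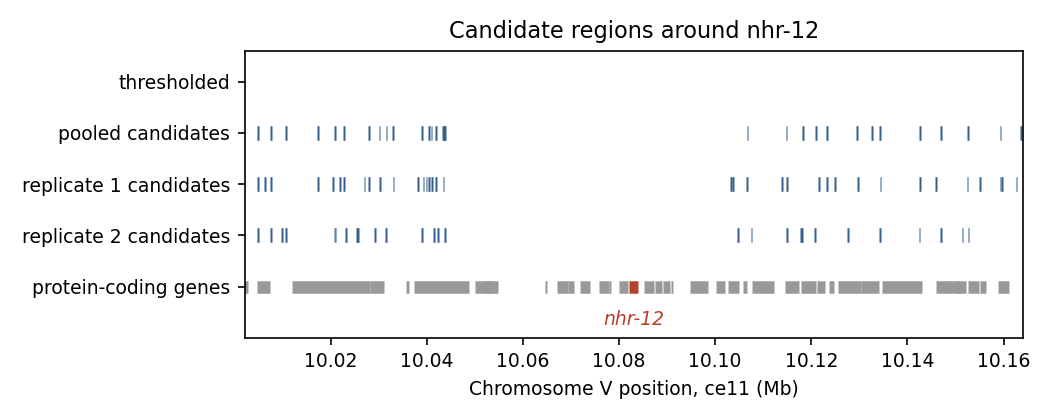
Map of chromosome V (horizontal, ce11 position in Mb) around nhr-12 with the thresholded peaks, the candidates of the pooled list and of each replicate (blue) and protein-coding genes (grey, nhr-12 in red). No candidate lies in a stretch of 62599 bp in the pooled list, and the gap spans about the same stretch in each replicate.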

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

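The comparisons with randomly drawn or GC-matched candidates, the opposite flank, protein-coding starts and the removal of tRNA peaks were chosen after seeing the data. The replicate overlap, replicate correlation, start-window share, GC difference, the histone, ribosomal protein, snoRNA and tRNA lists, and the CTGCGTCT, GC box and B box motifs kept their direction and their side of the threshold, where tested, under every alternative that gave a value. No finite odds ratio was obtained for CTGCGTCT with the 124 peaks with the largest signal, nor for the B box with 50 bp each side, without replicate 1 and with the opposite flank, where 0 flanks held the motif. The CACC box was a 5th enriched motif against candidates and with the opposite flank, but not against GC-matched candidates (1.42). The start-window odds ratio ran from 3.54 to 8.29, the GC difference from 4.99 to 11.7 percentage points and the replicate overlap from 34.1% to 49.2%. No ce10 annotation was used here, so the planned ce10 alternative for nhr-12 was not run. The ce10 thresholded list held 253 peaks, and 4 to 7 lists were over-represented across alternatives. Without replicate 2 only 4 of 6 were those of the main result: chaperones and snRNA were lost, and translation factors and tRNA synthetases and microRNA genes gained. The former list was also gained with 1 gene per peak, and microRNA with all annotated genes as background. With depth unknown, no limit can be set on weaker regions. For the changes below the cause was not tested, beyond the smaller sets that some alternatives leave.

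With the 124 peaks with the largest signal, odds ratios past no threshold were 1.38 for chromosome X, 4.96 for chaperones, 2.65 for snRNA, 5.50 for the GA repeat, 0.462 for the homeodomain core and 0 for the X-box, and 2 motifs were under-represented rather than 4. With each replicate left out of the tested regions in turn, the ranges were 1.22 to 1.28 for chromosome X, 2.70 to 6.405 for chaperones, 3.01 to 5.20 for snRNA, 0.0870 to 0.290 for pseudogenes, 0.355 to 0.417 for the homeodomain core, and 0.6 to 1.5, a reversal without replicate 2, for the X-box. In these settings 0 to 1 lists were under-represented. Without tRNA peaks chromosome X gave 1.17, and with 1 gene per peak chaperones gave 5.09. Pseudogenes had an observed to expected ratio of 0.225 against random candidates and 0.275 against GC-matched ones. The ratio was 0.132, past the threshold, against candidates matched on GC content and start window. With 50 bp each side, 2 motifs were under-represented, with 0.412 for the homeodomain core and 0 for the X-box. Candidates as background gave 0.705 and 0, and the opposite flank 0.591 and 0, for the same motifs. GC-matched candidates left 1 motif under-represented (AGTTCA), with 0.621 for GATA, 0 for the X-box, and reversed values of 1.39 for the T run and 1.82 for the homeodomain core.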

Other observations

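Tests by biotype and by class of peak were chosen after the data were seen, as were the tests of removal or extra control copies, of the position of nhr-12 and of AGGTCA sites below. The largest class of small RNA genes in the annotation behaved unlike the tRNA, snRNA and snoRNA genes. Only 11 of 3315 piRNA genes with a candidate had a peak (0.332% against 3.10% of other genes; odds ratio 0.104, 95% interval 0.0514 to 0.188, adjusted exact p = 8.08e-26 over 11 biotypes). Many piRNA genes lie close together and share candidates, so they are not independent. Other ncRNA genes had 99 of 3216 (3.08% against 2.33%; odds ratio 1.33, adjusted exact p = 0.0331), and protein-coding genes 189 of 7138 (2.65% against 2.35%, adjusted exact p = 0.303). The genes that both were compared with include the 3315 piRNA genes, whose low share lowers the comparison values. Neither comparison therefore shows an excess over genes other than piRNA genes. The microRNA list missed the threshold, and its 7 genes with a peak, named after their values were seen, were mir-51, mir-52, mir-55b, mir-56, mir-58a, mir-2 and mir-90. The mir-51 start lay in the window of the peak at F36H1.17, the 12th by signal.

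Of the 4 enriched motifs, the B box and the GC box differed between classes of peak. The B box was in 14 of the 25 peaks at tRNA genes (56.0%) and 4 of the 224 others (1.79%; odds ratio 66.3, 17.4 to 324, adjusted exact p = 1.15e-11 over 28 tests). This element is part of the tRNA gene sequence, so the difference follows from the choice of class and shows nothing beyond the presence of tRNA genes. The GC box was in 4 of 5 histone peaks and 42 of 244 others (adjusted exact p = 0.0420). Histone genes occur in near-identical copies, so these 5 peaks may not be independent and the p-value is uncertain. CTGCGTCT was in 28 of the 175 peaks at none of the 6 over-represented lists (16.0%) and in 4 of the 74 at these lists (5.41%), a difference that missed the threshold after adjustment (exact p = 0.0227, adjusted exact p = 0.159). Of the 25 peaks at tRNA genes, 14 lay on chromosome X (56.0%), as did 156 of the 354 candidates at tRNA genes (44.1%) and 47 of the 224 other peaks (20.98%).

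The candidate-free stretch around nhr-12 was the 5th longest of 26823 gaps in the pooled list, whose median is 2061 bp. Gaps as long covered 0.526% of the genome, which argues against a chance position of nhr-12 inside one, though with 4 longer gaps a chance gap between candidates cannot be excluded for the gap as such. Repeated sequence is unlikely as the cause: 2.18% of the stretch's 31-mers occurred elsewhere in the genome, against a median of 6.31% in 200 random stretches and 56.2% to 95.8% in the 4 longer gaps. What stays open is removal or extra control copies of the tagged region, since a transgene adds copies of the locus and could raise the control there, or the region could have been filtered. The 0 candidate summits within 15 kb of the gene in the replicate lists only restate the gap and do not decide it, the control and any filter were not analysed here, and no biological explanation was tested.

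The over-representation of histone, ribosomal protein, chaperone, tRNA, snRNA and snoRNA genes was weighed against base composition. Against candidates matched on GC content, 6 of the 6 lists kept p below 0.05 and more than 2 times the expected number of genes, and so did 6 of 6 against candidates matched on GC content and promoter location in general, with ratios from 2.26 for tRNA to 11.1 for histones. Both results argue against these as the whole cause, but unmatched ratios were larger, from 7.44 for tRNA to 40.7 for histones, and those matched on GC content alone ran from 4.53 to 23.9, lower than unmatched for every list but chaperones (18.1 against 15.2), so these factors go with part of the pattern. Of the 74 peaks at these lists, 6.76% (exact 95% interval 2.23 to 15.1) had AGGTCA within 100 bp, so most of them lacked this hexamer. Since only 13 of all 249 summits had it, a low share was known beforehand. The value therefore does not decide on nuclear receptor sites as a cause, and other forms of site remain possible. Still open and untested are recruitment of the tagged receptor by other proteins and a general tendency of highly transcribed loci to yield ChIP signal, which would need an untagged strain or other factors.

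In each replicate, 145 of the 249 best regions were not among the best of the other. Noise around the rank limit cannot be told apart from a real difference here: 79.3% of these regions were candidates in the other replicate, but their median ranks there were 1256 for those of replicate 1 and 2025 for those of replicate 2, between the bounds set beforehand. Regions of a different class may have contributed, since 75.9% of the regions of replicate 1 alone and 61.4% of those of replicate 2 alone lay in a gene start window, a difference of 14.5 percentage points (3.80 to 24.7; Fisher's exact test, p = 0.0112). The sets were alike in GC content (46.4% and 46.1%), closeness to tRNA genes (12 regions each within 50 bp) and chromosome X (33 and 32 regions). More regions of the replicate 1 set were candidates in the other replicate (84.8% against 73.8%) and thresholded peaks (76 against 50). The strongest regions were shared: of the 50 best in replicate 1, 37 were among the 249 best of replicate 2, and of the 50 best in replicate 2, 41 among those of replicate 1. Depth is unknown and stays open as a source of the difference.

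Of the 28574 pooled candidates, 3 were narrower than the common width of 356 bp, and these ranked 1 (124 bp, upstream of atx-2), 2 (103 bp, upstream of WBGene00014538) and 10 (118 bp, upstream of Y48G10A.3) by signal.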
